A study of Mus musculus with 15 samples.

How the data were processed

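Total RNA of the heart apex was amplified, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays of 4 per slide, per the labels' protocols. The 15 scanner files hold the intensity of each spot, written by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal is a background-subtracted intensity with no scaling between arrays, per the file headers. The deposited value table holds log2 values that the authors scaled to a shared distribution. Its scale was found by setting each column against the scanner values, and column medians lay between 7.22 and 7.23. How background was treated there is not given in the sources used here. The submitters' processing notes name limma, and its version is not given in the sources used here. Samples took their operation and genotype from title and source name. The description field contradicted these for the operation in 7 of 15 samples. The labels say 4 animals per group, and 15 samples were analysed here.

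Spots of 1 probe were averaged, control spots were left out, and spots with outlier flags were set missing. This gave 41174 probes. The files pair probes with accessions, which were named through a RefSeq gene table of the assembly GRCm38.p6, used for names and for the order of genes only. A symbol was found for 24844 probes (17178 symbols) and not for 16330. The main values were log2 of the processed signal minus each array's 75th percentile over all probes. A probe entered when it was well above background on 3 or more arrays, which left 32510. A gene took its brightest probe and an unnamed probe stood for itself, giving 25786 features, of which 14918 were named. Where a called gene had several probes, their signs differed for 23 of 381 genes in the TAC comparison filed as Cre, 316 of 1530 in that filed as KO and 24 of 178 between genotypes after TAC.

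limma 3.58.1 (R 4.3.3) fitted the 4 groups on all 15 arrays, and empirical Bayes tests with Benjamini-Hochberg adjustment called features at an adjusted p under 0.05 in each of 5 comparisons. Fold changes are log2 differences with moderated standard errors. limma's camera tested 33 gene lists of 5 or more measured members, with a preset correlation of 0.01 and, beside it, an estimated one. The tests, lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took Klf4, the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap (no such condition for the difference of responses), up to 4 members of each list described, and Nppa, Nppb, Myh7, Acta1, Ppargc1a and Esrra. Unnamed probes and provisional symbols were left out of it. The lists described are the 8 of smallest camera p in each comparison, and up to 2 members of each are named, choices made after seeing the data. The values of 1 gene that the rule names are not reported here, and counts over named genes leave it out. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

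The fit was tested on simulated data with 200 changed genes among 25725, 100 changed by 1 and 100 by 2 on the log2 scale. For TAC in arrays filed as Cre 22 and 51 of 100 were recovered, with 6 false calls among 79. For TAC in those filed as KO 22 and 62 were recovered, with 7 among 91. For genotype after sham 24 and 63 were recovered, with 12 among 99, and after TAC 24 and 63, with 5 among 92. For the difference of responses 1 and 36 were recovered, with 1 among 38. A list shifted by 0.5 in the first of these comparisons was called and 0 of the other lists were. The simulated genes were drawn independently of each other and without slide effects, so this does not test camera on lists of correlated genes. Each gene had the same spread on every array. An array standing apart like KO TAC replicate 4, or as many changes as were called after TAC, was not simulated. The recovered and false calls may differ there.

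Slides followed from the array barcodes, and the arrays were scanned on 1 day. Arrays on 1 slide deviated together from their group means, with a median correlation of 0.28 over 21 pairs and 0.42 over 18 pairs without KO TAC replicate 4, so slide was tested as a block and within slides. Within slides, 1532 of 1532, 5765 of 5978, 4 of 4 and 779 of 786 calls of the 4 comparisons between 2 groups had 1 sign on every slide that held both groups. The calls were made on the same arrays, so this agreement was likely in advance and is no independent test. No 2 arrays held identical values. Alternatives covered normexp with quantile normalization (on the median signal, since the mean signal was not used here), quantile and median scaling, the authors' values, other filters, slide and replicate blocks, the mean over probes, outlier spots kept, trended and robust variance, array weights, only the compared groups, each array left out, and the operation of the description field. Slide as a block without KO TAC replicate 4, and the authors' values under the genotypes of the scanner files, were added after seeing the data. For the latter the genotypes of all 15 columns were exchanged. The column of KO TAC replicate 4, which matched no scanner file, was so counted as Cre TAC by assumption. Which arrays came from separate animals is as the labels say, and the p-values measure the spread between these samples.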

Results

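Gene expression was measured in the heart apex of 10-week-old male mice, 3 days after transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure, or after a sham operation. The mice carried cre alone under a myosin heavy chain promoter (Cre) or cre together with deletion of Klf4, a zinc-finger transcription factor (KO). The 15 arrays fell into 4 Cre sham, 3 Cre TAC, 4 KO sham and 4 KO TAC samples, 1 animal's heart per array as far as the labels say. On 14 arrays the median processed signal lay between 88.2 and 147.1 and the share of probes well above background between 66.1% and 75.7%. KO TAC replicate 4 had a median signal of 453.9 and 96.0% of probes well above background, and its median correlation with the other arrays was 0.807, against 0.961 to 0.982 for the others. It was kept in each comparison, and the counts of called features without it are given beside those with it. No probe was saturated, and the number of arrays limits the precision.

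**Figure D1:**
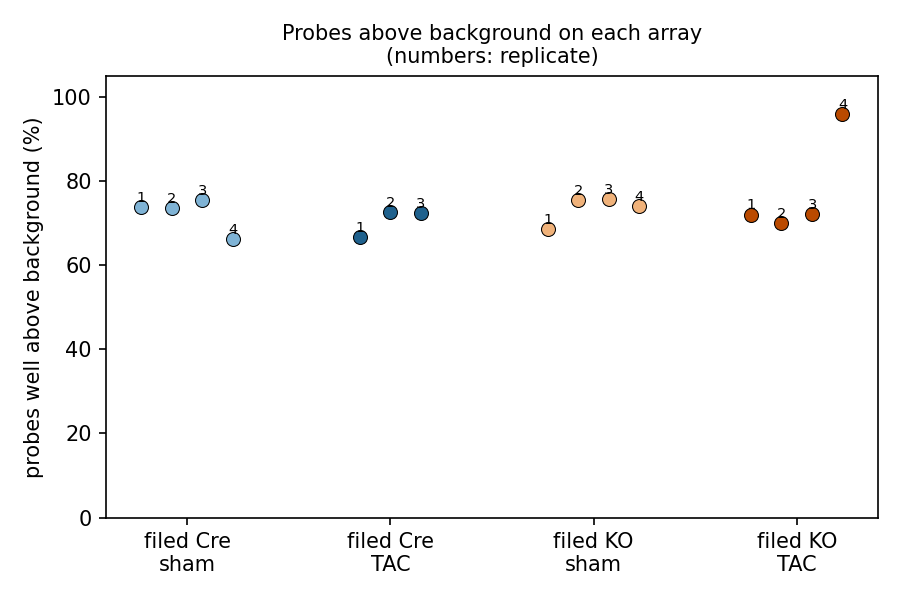
Percentage of probes well above background on each array (y axis), by group as filed with the scanner files (x axis), 1 point per array with its replicate number. KO TAC replicate 4 lies at 96.0% and the other 14 arrays lie between 66.1% and 75.7%.

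The direction of every genotype difference is unsettled. For 14 of the 15 scanner files the same array was found in the deposited value table, at a rank correlation of at least 0.99999, and all 14 stood there under the other genotype and the same operation. The groups below follow the scanner files and are called filed as Cre and filed as KO. With the labels of the value table, each sign of a genotype difference turns. After TAC this holds if the label of KO TAC replicate 4, whose scanner file matched no column, turns too. Features called between genotypes after sham argue that it does. Hdhd3 read 1.332 (log2) on that array, and at most 0.389 on any array filed as Cre. The unnamed probes A_51_P370073 and A_52_P458141 had TAC means of -4.08 ± 0.48 and -5.68 ± 0.65 filed as KO, that array included (SD, n = 4). Filed as Cre these were -0.79 ± 0.41 and -3.48 ± 0.16 (SD, n = 3). A further called probe lay near background and is left out. The targeted gene did not settle the direction. The single Klf4 probe read 3.98 ± 0.25 (SD, n = 4) in sham and 4.14 ± 0.13 (SD, n = 3) in TAC arrays filed as Cre, on the log2 scale relative to the array's 75th percentile. In arrays filed as KO it read 3.94 ± 0.51 (SD, n = 4) after sham and 4.15 ± 0.44 (SD, n = 4) after TAC. The differences between genotypes were -0.045 ± 0.27 (SE) after sham and 0.017 ± 0.29 after TAC, with limma adjusted p of 1.0 and 0.98. After TAC against sham Klf4 differed by 0.15 ± 0.29 in arrays filed as Cre and 0.21 ± 0.27 in those filed as KO, neither past the threshold. Whether the probe lies in the deleted part of the gene is not given in the sources used here, so it may check nothing. Total RNA of the apex may also hold Klf4 from cells in which cre was not active, which was not tested. For 7 arrays 1 label names the other operation. Grouped by that label, limma called 0 features for TAC in either genotype, with 40 and 2514 at an unadjusted p under 0.05, against 1532 and 5978 called by title.

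The first comparison asked which genes pressure load changed in hearts filed as Cre. Most matrix and cell division genes of the lists fixed in advance rose. Cthrc1, a secreted protein linked to collagen, was at least 73.5-fold higher after TAC (adjusted p = 0.0020), and Chil1, a chitinase-like protein, at least 52.1-fold (adjusted p = 0.00020). Dmkn, Crct1 and Arg1, the last encoding arginase, were at least 83.4-fold, 39.4-fold and 38.4-fold higher, with adjusted p of 0.00023, 0.015 and 0.0045. These bounds set the TAC mean against the lowest signal well above background, since none of the 4 sham arrays read these genes well above background. Dmkn had 2 probes, at 0.96 and 6.84 on the log2 scale, and the bound is that of the brighter. Cre TAC replicate 3 read Crct1 and Arg1 at -5.24 and -4.94. Replicates 1 and 2 read 0.040 and 1.90 for Crct1 and 0.96 and 0.57 for Arg1. Saa3, an acute-phase serum amyloid well above background on 3 of 4 sham arrays, rose by 8.71 ± 1.03 on the log2 scale (SE, adjusted p = 0.0012), and Nmrk2, a nicotinamide riboside kinase of muscle, by 6.59 ± 0.84, adjusted p = 0.0014. The largest falls were in Ces1d (-3.77), Retnla (-3.76), Inmt (-3.74), Car3 (-3.25), Cfd (-3.18), Helt (-2.97), Phkg1 (-2.94) and Kcnv2 (-2.76), all log2 folds with adjusted p from 0.0037 to 0.044. Car3, well above background on 2 of 3 TAC arrays, is a carbonic anhydrase, Cfd the adipocyte protease adipsin, and Kcnv2 a potassium channel subunit. Without Cre TAC replicate 2, Ces1d was at -2.48 and the calls of Crct1, Retnla, Car3, Cfd, Helt, Phkg1 and Kcnv2 ended (adjusted p from 0.060 to 0.27). The call of Crct1 ended without Cre TAC replicate 1 as well (adjusted p = 0.079). Leaving out 1 array at a time ended the calls of Car3, Cfd and Phkg1 for 6, 10 and 4 of the 15 arrays.

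Of 37 measured extracellular matrix genes 28 rose and 0 fell (median log2 fold of 2.21, 2.28 with slide as a block and 1.27 to 2.86 within slides, camera adjusted p = 2.2e-34, adjusted p = 0.11 with an estimated correlation), among them Tnc (6.44 ± 0.71, adjusted p = 0.0012) and Spp1 (5.84 ± 0.96, adjusted p = 0.0039), which encode tenascin C and osteopontin. Adjusted over the list alone, 33 passed. Of 30 DNA replication and mitosis genes 23 rose, 24 adjusted over the list alone (median log2 fold of 2.36, 2.37 with slide as a block and 1.39 to 3.26 within slides, camera adjusted p = 4.2e-29, adjusted p = 0.11 with an estimated correlation), with Ccnb1 at 4.36 ± 0.62 and Aurkb at 3.28 ± 0.79, well above background on 3 and 2 of 4 sham arrays. Of 27 macrophage and monocyte markers 12 rose, 25 adjusted over the list alone (median log2 fold of 1.29, 1.37 with slide as a block and 0.25 to 1.84 within slides, camera adjusted p = 5.1e-17, adjusted p = 0.15 with an estimated correlation), with Chil3 at 5.59 ± 0.98. Of 14 neutrophil markers 5 rose, 8 adjusted over the list alone (median log2 fold of 3.07, 2.58 with slide as a block and 1.84 to 2.94 within slides, camera adjusted p = 3.9e-07, adjusted p = 0.15 with an estimated correlation). Among them Il1r2 was at least 12.7-fold higher and Clec4e, well above background on 1 of 4 sham arrays, rose by 4.33 ± 0.64. That size depends on the background. Of 38 inflammatory cytokine and chemokine genes 12 rose and 2 fell, 21 and 2 adjusted over the list alone (median log2 fold of 1.32, 1.42 with slide as a block and 0.35 to 1.81 within slides, camera adjusted p = 1.8e-09, adjusted p = 0.16 with an estimated correlation), with Lcn2 at 4.52 ± 0.62 and Serpina3n at 4.23 ± 0.74. Of 23 hypertrophy and fetal genes 11 rose, 16 adjusted over the list alone (median log2 fold of 1.21, 1.35 with slide as a block and 0.93 to 1.70 within slides, camera adjusted p = 3.9e-13, adjusted p = 0.15 with an estimated correlation). Nppb, the B-type natriuretic peptide, rose by 2.38 ± 0.40, Nppa by 2.06 ± 0.33, Ccn2 by 2.30 ± 0.43 and Acta1 by 1.80 ± 0.49, with adjusted p of 0.0047, 0.0033, 0.0080 and 0.048. Myh7 differed by 0.62 ± 0.38 (adjusted p = 0.47). Of 77 cytosolic ribosomal protein genes 4 rose, 3 adjusted over the list alone (median log2 fold of 0.39, 0.40 with slide as a block and 0.27 to 0.54 within slides, camera adjusted p = 1.5e-13, adjusted p = 0.43 with an estimated correlation), with Rpl3 at 1.52 ± 0.29 and Rpl22l1 at 1.05 ± 0.26. Of 20 genes of branched-chain amino acid degradation 1 fell, 7 adjusted over the list alone (median log2 fold of -0.65, -0.63 with slide as a block and -0.99 to -0.36 within slides, camera adjusted p = 2.4e-06, adjusted p = 0.43 with an estimated correlation), and that gene was Ppm1k at -1.16 ± 0.26. Ppargc1a and Esrra, regulators of mitochondrial genes, differed by 0.42 ± 0.22 and -0.31 ± 0.22, with adjusted p of 0.35 and 0.57. The 8 list medians had 1 sign on each of the 3 slides. Leaving out KO TAC replicate 4, 21 cytosolic ribosomal genes rose and 1 fell, 52 and 1 adjusted over the list alone. There 4 branched-chain genes fell, 7 adjusted over the list alone. In the other 6 lists, in the order given, 31, 23, 16, 6, 16 and 14 rose. Camera set 11 of 33 lists higher and 9 lower. Among them were fibroblast markers (median log2 fold of 0.36, camera adjusted p = 0.0089, adjusted p = 0.53 with an estimated correlation), endothelial markers (median log2 fold of -0.26, camera adjusted p = 0.039, adjusted p = 0.75 with an estimated correlation) and lymphocyte markers (median log2 fold of -0.97, camera adjusted p = 0.00078, adjusted p = 0.53 with an estimated correlation). Of their members 5 of 18 rose and 1 fell, 1 of 20 fell and 2 of 19 fell. Adjusted over the list alone these were 5 and 1, 1 and 4, and without KO TAC replicate 4 they were 8 and 3, 2 and 7. Without Cre TAC replicate 2 the calls of Aurkb, Ccn2, Acta1, Rpl3, Rpl22l1 and Ppm1k ended (adjusted p from 0.060 to 0.20). Leaving out 1 array at a time ended those of Acta1, Rpl22l1, Aurkb and Ppm1k for 11, 6, 4 and 4 of the 15 arrays. Cre TAC replicate 3, which read Crct1 and Arg1 low, read Spp1, Chil3 and Tnc at -0.82, -1.39 and -0.36. Replicate 1 read them at 3.84, 3.00 and 1.81 and replicate 2 at 3.84, 2.69 and 2.23. Replicate 3 read Nppb at 7.64, above the 7.58 and 7.31 of replicates 1 and 2, so not every rise was weaker there.

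In all, 1109 features rose and 423 fell of 25786 tested (limma, adjusted p under 0.05). Without KO TAC replicate 4 the counts were 2046 and 1440, with slide as a block 1319 and 697, and with normexp and quantile normalization 1100 and 791, which moved the share of rises from 72.4% to 58.2%. Median scaling gave 614 and 185, a share of 76.8%. A replicate block gave 718 and 217, slide as a random block 1539 and 803 and array weights 2399 and 1698. The authors' values gave 3992 and 4645 with genotypes as labelled there, and 2618 and 3247 with those of the scanner files. The count of 1532 became 413 without Cre TAC replicate 2, 617 without Cre TAC replicate 1, 776 without Cre sham replicate 3, 846 without Cre sham replicate 2 and 1018 without Cre sham replicate 1.

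The same question was asked in hearts filed as KO. Arg1 rose by 8.98 ± 1.06 on the log2 scale (SE, adjusted p = 0.00017), and Crct1 by 7.76 ± 1.36. These sizes depend on the background, since 1 and 2 of 4 sham arrays read them well above it. Cxcl3, a neutrophil-attracting chemokine that no sham array read well above background, was at least 26-fold higher (adjusted p = 0.00020). Saa3 (6.75), Il6 (6.14), Chil4 (6.0), Chil3 (5.89) and Wfdc21 (5.64) rose as well, with adjusted p from 0.00041 to 0.00088. The largest falls were in Inmt (-4.29), Cngb3 (-4.15), Pla2g5 (-4.01), Fn3k (-3.94), Asb14 (-3.88), Dbp (-3.69), Kcnv2 (-3.66) and Ces1d (-3.63), with adjusted p from 3.9e-05 to 0.0028. Saa3, Il6 and Chil4 were well above background on 3 of 4 sham arrays and Wfdc21 on 2 of 4. Cngb3 and Kcnv2 were so on 1 of 4 TAC arrays each, so the sizes of their falls depend on the background. Fn3k encodes fructosamine 3 kinase and Dbp a clock-controlled transcription factor.

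Of 24 interferon-response genes 17 fell, 19 adjusted over the list alone (median log2 fold of -1.13, -1.13 with slide as a block and -1.60 to -0.76 within slides, camera adjusted p = 4.1e-11, adjusted p = 0.28 with an estimated correlation), with Iigp1 at -2.32 ± 0.30 and Cmpk2 at -2.16 ± 0.24. Of 20 genes of branched-chain amino acid degradation 15 fell, 18 adjusted over the list alone (median log2 fold of -1.21, -1.21 with slide as a block and -1.89 to -0.24 within slides, camera adjusted p = 6.8e-10, adjusted p = 0.28 with an estimated correlation), with Ppm1k at -1.93 ± 0.24 and Mccc1 at -1.75 ± 0.34. Of 36 genes of respiratory complex I 13 fell, 27 adjusted over the list alone (median log2 fold of -0.63, -0.63 with slide as a block and -1.26 to 0.016 within slides, camera adjusted p = 1.6e-09, adjusted p = 0.41 with an estimated correlation), with Ndufb5 at -1.08 ± 0.20. Of 78 mitochondrial ribosomal protein genes 25 fell and 2 rose, 35 and 4 adjusted over the list alone (median log2 fold of -0.48, -0.48 with slide as a block and -1.20 to 0.052 within slides, camera adjusted p = 6.5e-09, adjusted p = 0.48 with an estimated correlation), with Mrps25 at -1.61 ± 0.24 and Mrpl49 at -1.31 ± 0.22. Of 25 genes of the tricarboxylic acid cycle 9 fell, 17 adjusted over the list alone (median log2 fold of -0.66, -0.66 with slide as a block and -1.43 to 0.16 within slides, camera adjusted p = 2.9e-07, adjusted p = 0.41 with an estimated correlation), with Sdha at -1.30 ± 0.32 and Idh2 at -1.17 ± 0.29. KO TAC replicate 4 differed from the other KO TAC arrays in these lists by a median of -0.29, -0.90, -0.72, -0.82 and -0.83, and without it the medians were -1.18, -0.93, -0.43, -0.28 and -0.48, all still past camera's threshold at the preset correlation (adjusted p = 0.32, 0.34, 0.52, 0.54 and 0.52 with an estimated correlation). In that fit 18, 13, 9, 24 and 7 of their genes fell, 20, 15, 9, 25 and 7 adjusted over the list alone. Of the mitochondrial ribosomal genes 7 rose there, also 7 adjusted over the list alone. With all arrays, the other probe of Mrps25 was at -0.071. The medians of complex I, mitochondrial ribosomal proteins and the cycle were above 0 on 1 of 4 slides. Markers of other cell types were lower beside these lists. Endothelial markers had a median log2 fold of -0.56, camera adjusted p = 0.0079, adjusted p = 0.51 with an estimated correlation, with 5 of 20 falling, 6 adjusted over the list alone. Fibroblast markers had a median log2 fold of -0.65, camera adjusted p = 0.023, adjusted p = 0.49 with an estimated correlation, with 8 of 18 falling and 4 rising, 10 and 5 adjusted over the list alone. Smooth muscle and pericyte markers had a median log2 fold of -0.60, camera adjusted p = 0.0094, adjusted p = 0.43 with an estimated correlation, with 9 of 18 falling and 2 rising, 10 and 2 adjusted over the list alone. Red blood cell markers had a median log2 fold of -1.04, camera adjusted p = 0.043, adjusted p = 0.47 with an estimated correlation, with 2 of 7 falling, 5 adjusted over the list alone. Adipocyte and mesothelial markers were higher (median log2 fold of 0.98, camera adjusted p = 0.020, adjusted p = 0.28 with an estimated correlation), 8 of 15 rising and 1 falling, 8 and 2 adjusted over the list alone. KO TAC replicate 4 left out, the medians of these 5 lists were -0.28, -0.46, -0.43, -0.80 and 1.21, with camera adjusted p of 0.26, 0.16, 0.24, 0.092 and 0.059. Lymphocyte markers passed camera only in that fit, at a median of -1.04 (camera adjusted p = 0.0024, adjusted p = 0.48 with an estimated correlation), against -0.19 with the array (camera adjusted p = 0.10). Of 19 members 2 fell with it and 6 without it, 1 and 7 adjusted over the list alone. Macrophage and monocyte markers also passed only there, at a median of 0.42 (camera adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation), against 0.39 with it (camera adjusted p = 0.0504). Ppargc1a fell by 1.0 ± 0.21 (adjusted p = 0.0038) and Esrra by 0.72 ± 0.20 (adjusted p = 0.022), a call that ended without KO sham replicate 4 or KO TAC replicate 2 (adjusted p = 0.074 and 0.056). Camera set 9 of 33 lists higher and 14 lower, and 11 and 10 without KO TAC replicate 4.

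Of 30 DNA replication and mitosis genes 25 rose, also 25 adjusted over the list alone (median log2 fold of 1.89, 1.89 with slide as a block and 1.59 to 2.03 within slides, camera adjusted p = 2.4e-14, adjusted p = 0.28 with an estimated correlation), with Ccnb1 at 3.71 ± 0.57 and Top2a at 2.85 ± 0.43. Of 37 extracellular matrix genes 27 rose and 1 fell, 30 and 2 adjusted over the list alone (median log2 fold of 1.70, 1.70 with slide as a block and 0.86 to 1.85 within slides, camera adjusted p = 1.9e-10, adjusted p = 0.28 with an estimated correlation), with Spp1 at 5.05 ± 0.89 and Tnc at 4.81 ± 0.66. Neutrophil markers moved with them, 9 of 14 rising, 12 adjusted over the list alone (median log2 fold of 3.37, 3.37 with slide as a block and 2.25 to 4.78 within slides, camera adjusted p = 6.3e-07, adjusted p = 0.28 with an estimated correlation), with Il1r2 at 4.86 ± 0.66 and Retnlg at 4.57 ± 0.88, each well above background on 3 of 4 sham arrays. Leaving out KO TAC replicate 4, 28, 29 and 9 genes of these 3 lists rose, 28, 30 and 9 adjusted over the list alone. Nppb rose by 1.46 ± 0.37, adjusted p = 0.013. Nppa, Acta1 and Myh7 differed by 0.56 ± 0.30, 0.64 ± 0.45 and -0.47 ± 0.35, with adjusted p of 0.22, 0.36 and 0.38. In all, 2730 features rose and 3248 fell, against 3811 and 4298 without KO TAC replicate 4 and 3343 and 4079 with slide as a block. Median scaling gave 1504 and 2564, array weights 4770 and 5758, and these 8 arrays alone 1509 and 1625. The median fold of all features was 0.11 on the log2 scale, and -0.15 with quantile normalization, -0.073 with median scaling, -0.059 with normexp and -0.091 without KO TAC replicate 4.

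The TAC responses of both genotypes overlapped. Of the features that rose in arrays filed as Cre, 887 also rose in those filed as KO, where independent lists would share 117.4. Of those that fell, 376 fell in both, against 53.3. The folds correlated at r = 0.66 across all 25786 features, which are not independent replicates. Without KO TAC replicate 4, 1568 rose and 1195 fell in both, against 302.4 and 240.0, and r was 0.76. The comparisons shared no arrays but shared slides.

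**Figure D2:**
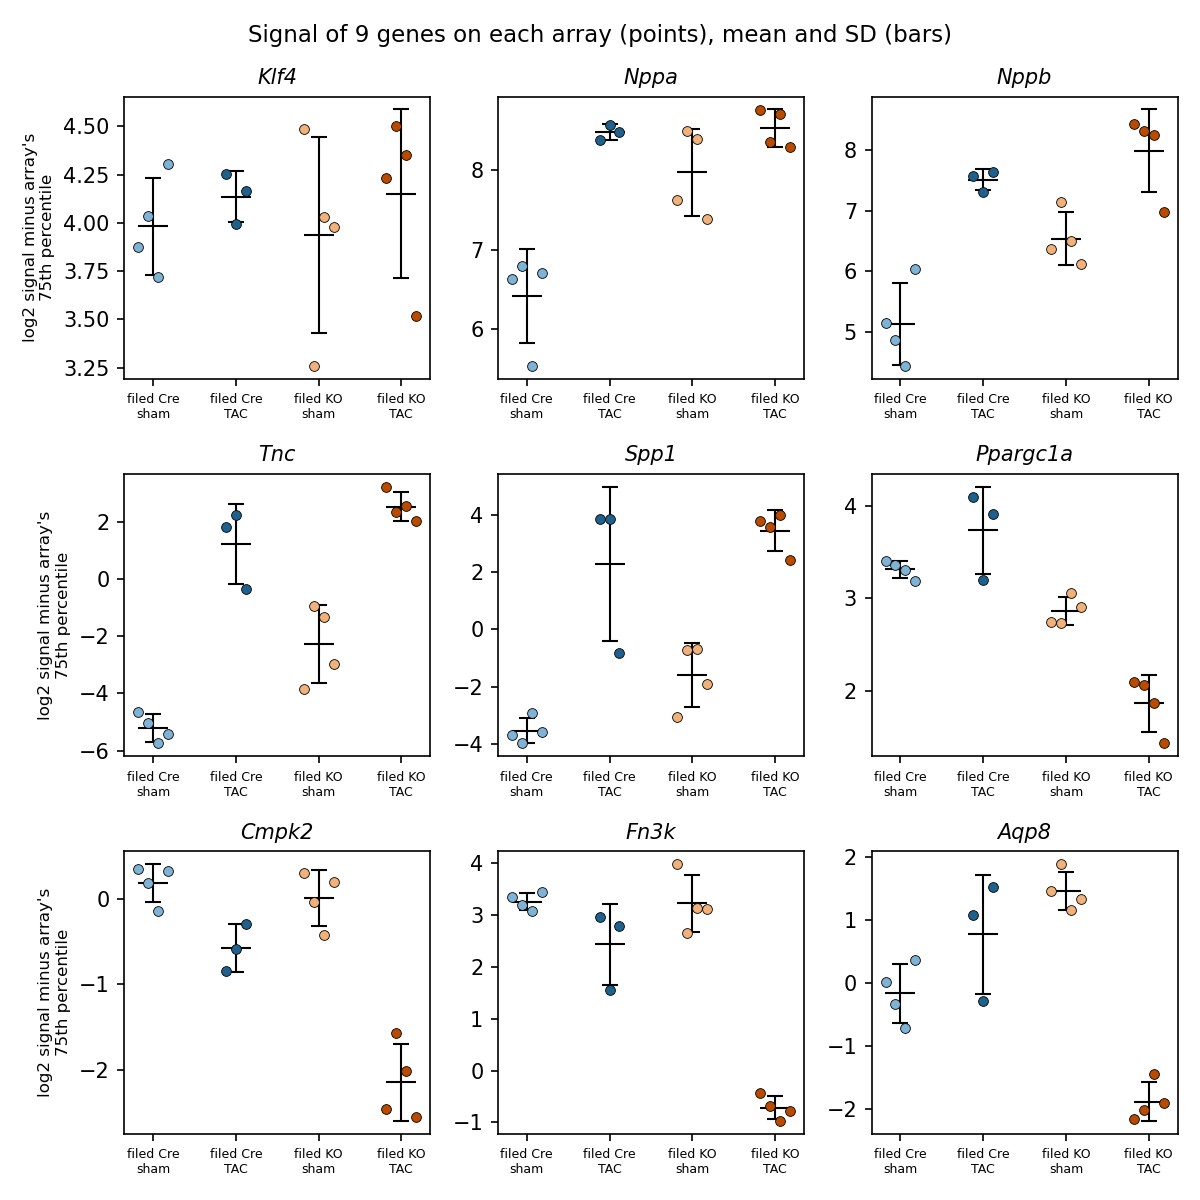
Log2 signal relative to the array's 75th percentile (y axes) of 9 genes in the 4 groups as filed with the scanner files (x axes), 1 point per array, with bars for the mean and SD. Ppargc1a, Cmpk2, Fn3k and Aqp8 lay lower in the TAC arrays filed as KO than in every array of the other groups.

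The genotype comparison after sham asked what Klf4 deletion changed without pressure load. Of 25786 features 1 was higher and 3 were lower in arrays filed as KO (limma), and the sign turns with the value table's labels. The higher gene was Hdhd3, a hydrolase-like protein, at 1.51 ± 0.13 (SE, adjusted p = 0.00046). The lower features were 3 unnamed probes. A_51_P370073 and A_52_P458141 were at -2.50 ± 0.25 and -2.37 ± 0.27, with adjusted p of 0.0012 and 0.0060. A_52_P908036, not well above background on any sham array filed as KO, was at least 3.07-fold lower (adjusted p = 0.00046). At an unadjusted p under 0.05 there were 1207 features. No list member passed, while camera's preset correlation set 9 lists higher and 2 lower, in all 6 lists without KO sham replicate 2 and 17 without KO sham replicate 1. Extracellular matrix genes had a median log2 fold of 0.61, 0.61 with slide as a block and 0.31 to 1.31 within slides, camera adjusted p = 2.4e-18, adjusted p = 0.31 with an estimated correlation, and 8 passed adjusted over the list alone. Tnc and Cilp differed by 2.94 ± 0.66 and 1.77 ± 0.45. Hypertrophy and fetal genes had a median log2 fold of 0.69, 0.69 with slide as a block and 0.16 to 1.40 within slides, camera adjusted p = 2.1e-14, adjusted p = 0.31 with an estimated correlation, with 4 adjusted over the list alone and 9 without KO TAC replicate 4. Nppa and Ankrd1 differed by 1.56 ± 0.30 and 1.0 ± 0.21, with adjusted p of 0.34 and 0.36. Nppb, Acta1, Myh7, Ppargc1a and Esrra differed by 1.41, 1.63, 0.44, -0.45 and -0.093, none past the threshold. Macrophage and monocyte markers had a positive median (median log2 fold of 0.64, 0.64 with slide as a block and 0.36 to 0.92 within slides, camera adjusted p = 8.0e-12, adjusted p = 0.40 with an estimated correlation), with Mpeg1 at 1.25 ± 0.39 and Ms4a7 at 1.04 ± 0.36. So did inflammatory genes (median log2 fold of 0.44, 0.44 with slide as a block and 0.14 to 0.90 within slides, camera adjusted p = 6.8e-09, adjusted p = 0.31 with an estimated correlation), with Serpina3n at 2.50 ± 0.69 and Il1rn at 2.40 ± 0.73 (well above background on 1 of 4 arrays filed as Cre and 3 of 4 filed as KO), and neutrophil markers (median log2 fold of 0.61, 0.61 with slide as a block and -0.40 to 2.47 within slides, camera adjusted p = 0.0019, adjusted p = 0.52 with an estimated correlation), with Clec4d at 2.20 ± 0.57 and Clec4e at 1.83 ± 0.59 (also on 1 and 3 of 4), though the neutrophil median had this sign on 2 of 4 slides. Cytosolic ribosomal proteins (median log2 fold of 0.13, 0.13 with slide as a block and 0.10 to 0.22 within slides, camera adjusted p = 4.2e-06, adjusted p = 0.85 with an estimated correlation), with Rpl3 at 0.63 and Rps27l at 0.33, and growth factor genes (median log2 fold of 0.38, 0.38 with slide as a block and -0.057 to 0.56 within slides, camera adjusted p = 0.0017, adjusted p = 0.51 with an estimated correlation), with Fstl1 at 0.86, had positive medians too. So did fibroblast markers (median log2 fold of 0.26, camera adjusted p = 0.0035, adjusted p = 0.63 with an estimated correlation), with 0 of 18 adjusted over the list alone. Fgf21, not well above background on any sham array filed as Cre, read at least 3.6-fold above them in arrays filed as KO, 3 of 4 of them well above background, and did not pass (adjusted p = 0.84). Branched-chain amino acid genes had a negative median (median log2 fold of -0.25, -0.25 with slide as a block and -0.64 to 0.056 within slides, camera adjusted p = 0.0011, adjusted p = 0.84 with an estimated correlation), with Bcat2 at -0.45 and Ppm1k at -0.47. The growth factor and branched-chain medians had 1 sign on 3 of 4 slides. Without KO sham replicate 2 they were 0.23 and -0.071 and no longer passed camera (adjusted p = 0.088 and 0.14). Those of hypertrophy and inflammatory genes were then 0.46 and 0.23. The inflammatory median was 0.29 without Cre sham replicate 3. The neutrophil median was 0.095 without KO sham replicate 4 (camera adjusted p = 0.18), 0.21 without Cre sham replicate 2 and 1.26 without KO sham replicate 2. Adjusted over the list alone, 1 of 14 neutrophil markers passed, and 0 members did in the macrophage, inflammatory, ribosomal, growth factor and branched-chain lists. Array weights gave 704 calls. Slide as a block gave 4, of which 3 were among the 4 reported. Quantile normalization gave 1 higher and 1 lower, median scaling 3 and 3, and the authors' values by the scanner files' genotypes 13 and 25. Without KO sham replicate 1 there were 8 and without KO TAC replicate 4 there were 6.

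The genotype comparison after TAC asked how the loaded hearts differed. Ppargc1a, a coactivator of mitochondrial genes, was lower in arrays filed as KO, at a log2 difference of -1.88 ± 0.22 (SE, adjusted p = 0.0026). Each sign here turns with the value table's labels, if that of KO TAC replicate 4 turns too, as its reading of Hdhd3 argues. Asb10 (-2.82 ± 0.27), Fn3k (-3.15 ± 0.34), Gbp6 (-3.40 ± 0.48), Ip6k3 (-2.91 ± 0.44), Lrrc52 (-3.0 ± 0.58), Aqp8 (-2.66 ± 0.38) and Pacsin1 (-2.63 ± 0.55) were the largest falls, with adjusted p from 0.00062 to 0.025. The other probe of Fn3k was at -0.75, and the probes of Pacsin1 ran from -2.63 to -0.70. Papln, which no array filed as KO TAC read well above background, was at least 1.99-fold lower (adjusted p = 0.019). The chemokine Cxcl3 was higher by 4.34 ± 0.92, adjusted p = 0.026. Cxcl2, Csf3, Slc6a19 and P2ry10, not well above background on any TAC array filed as Cre, were at least 5.24-fold, 4.22-fold, 3.78-fold and 2.3-fold higher, with adjusted p of 0.0025, 0.032, 0.012 and 0.029. Masp1, Fam24b and Lce1f were higher by 3.62 ± 0.60, 3.12 ± 0.51 and 3.10 ± 0.64. The sizes of Masp1 and Cxcl3 depend on the background, since 1 and 2 of 3 TAC arrays filed as Cre read them well above it. That of Lrrc52 does too, since it was well above background on 1 of 4 TAC arrays filed as KO. Cre TAC replicate 3 read Cxcl3 at -8.62, and replicates 1 and 2 read -4.45 and -5.31. Csf3 was well above background on 3 of 4 TAC arrays filed as KO and Papln on 2 of 3 filed as Cre. Without Cre TAC replicate 3 the calls of Lrrc52, Pacsin1, Papln, Cxcl3, Csf3, Slc6a19, P2ry10, Masp1, Fam24b and Lce1f ended (adjusted p from 0.068 to 0.17). Without Cre TAC replicate 1 this held for all of these but Papln and Cxcl3 (adjusted p from 0.054 to 0.13).

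Of 24 interferon-response genes 8 were lower, 21 adjusted over the list alone (median log2 fold of -1.06, -0.98 with slide as a block and -1.19 to -0.36 within slides, camera adjusted p = 4.9e-16, adjusted p = 0.40 with an estimated correlation), with Ifit3 at -1.58 ± 0.31 and Cmpk2 at -1.57 ± 0.26. Of 26 regulators of mitochondrial biogenesis and dynamics 6 were lower, 8 adjusted over the list alone (median log2 fold of -0.31, -0.34 with slide as a block and -0.66 to -0.36 within slides, camera adjusted p = 4.9e-06, adjusted p = 0.41 with an estimated correlation), with Esrrb at -1.31 ± 0.27. Of 18 fibroblast markers 4 were lower, 10 adjusted over the list alone (median log2 fold of -0.79, -0.86 with slide as a block and -0.90 to -0.53 within slides, camera adjusted p = 5.3e-07, adjusted p = 0.41 with an estimated correlation), with Islr at -1.63 ± 0.22 and Fbln1 at -1.47 ± 0.31. Of 20 branched-chain amino acid genes 2 were lower, 9 adjusted over the list alone (median log2 fold of -0.73, -0.74 with slide as a block and -0.99 to -0.83 within slides, camera adjusted p = 2.0e-09, adjusted p = 0.41 with an estimated correlation), with Oxct1 at -1.37 ± 0.31 and Ppm1k at -1.24 ± 0.26. Mitochondrial ribosomal proteins had 1 of 78 lower, 6 adjusted over the list alone (median log2 fold of -0.41, -0.42 with slide as a block and -0.83 to -0.33 within slides, camera adjusted p = 2.2e-10, adjusted p = 0.48 with an estimated correlation), which was Mrps25 at -1.17 ± 0.26. The tricarboxylic acid cycle had 1 of 25 lower, also 1 adjusted over the list alone (median log2 fold of -0.48, -0.49 with slide as a block and -0.84 to -0.51 within slides, camera adjusted p = 7.0e-08, adjusted p = 0.48 with an estimated correlation), which was Ogdh at -0.96 ± 0.21. Complex I had 0 of 36, also 0 adjusted over the list alone (median log2 fold of -0.40, -0.41 with slide as a block and -0.68 to -0.40 within slides, camera adjusted p = 3.0e-08, adjusted p = 0.48 with an estimated correlation), with Ndufb5 at -0.83 ± 0.21. Complexes III, IV and V had 0 of 35, also 0 adjusted over the list alone (median log2 fold of -0.35, -0.37 with slide as a block and -0.66 to -0.33 within slides, camera adjusted p = 7.7e-06, adjusted p = 0.48 with an estimated correlation), with Atp5d at -0.65 ± 0.27 and Uqcrc2 at -0.60 ± 0.26. The other probes of Islr and Mrps25 were at -0.75 and -0.40. The camera adjusted p of complexes III, IV and V was 0.062 without KO TAC replicate 4. There the medians of these complexes, complex I, mitochondrial ribosomal proteins and the cycle were -0.17, -0.21, -0.20 and -0.30. In the 8 lists, in the order given, 10, 6, 6, 3, 4, 1, 1 and 0 genes were lower in that fit, 22, 8, 8, 8, 6, 1, 0 and 0 adjusted over the list alone. Higher were 4 mitochondrial ribosomal genes and 1 of the regulators, also 4 and 1 adjusted over the list alone. Without Cre TAC replicate 3 the median of the biogenesis and dynamics regulators was -0.20. In the same fit the calls of Ifit3, Cmpk2, Esrrb, Fbln1, Oxct1, Ppm1k, Mrps25 and Ogdh ended (adjusted p from 0.086 to 0.18). Leaving out 1 array at a time ended the calls of Oxct1 and Mrps25 for 7 and 6 of the 15 arrays. All 8 medians were negative on the 3 slides. Camera set 6 of 33 lists higher and 17 lower, and 8 and 8 without KO TAC replicate 4. The lower lists included smooth muscle and pericyte markers (median log2 fold of -0.39, camera adjusted p = 0.00035, adjusted p = 0.41 with an estimated correlation). Endothelial markers (median log2 fold of -0.25, camera adjusted p = 0.024, adjusted p = 0.56 with an estimated correlation) and adult contraction genes (median log2 fold of -0.30, camera adjusted p = 0.00036, adjusted p = 0.48 with an estimated correlation) were lower lists too. Of their members 1 of 18, 1 of 20 and 0 of 22 were lower, 5, 1 and 2 adjusted over the list alone. Lymphocyte markers were among the higher lists (median log2 fold of 0.73, camera adjusted p = 0.011, adjusted p = 0.56 with an estimated correlation), with 0 of 19 past the threshold, also 0 adjusted over the list alone. Neutrophil markers were higher (median log2 fold of 1.38, camera adjusted p = 0.00034, adjusted p = 0.41 with an estimated correlation), and macrophage (median log2 fold of -0.34, camera adjusted p = 0.023, adjusted p = 0.58 with an estimated correlation) and red blood cell markers (median log2 fold of -0.70, camera adjusted p = 0.037, adjusted p = 0.48 with an estimated correlation) lower. Of their members 0 of 14, 1 of 27 and 0 of 7 passed, 0, 2 and 0 adjusted over the list alone. The camera adjusted p of these 3 lists was 0.0012, 0.32 and 0.16 without KO TAC replicate 4, where the first had an adjusted p = 0.51 with an estimated correlation. That of the 4 lists before them was 0.15, 0.83, 0.16 and 0.40 without KO TAC replicate 4. The endothelial and adult contraction medians were then -0.057 and -0.15. Nppa, Nppb, Myh7, Acta1 and Esrra differed by 0.051, 0.48, -0.64, 0.47 and -0.50, none past the threshold, and Nppa was at -0.074 with slide as a block and -0.066 with median scaling.

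In all, 295 features were higher and 491 lower, against 1060 and 1217 without KO TAC replicate 4 and 508 and 861 with slide as a block. Median scaling gave 80 and 158, a replicate block 119 and 183, no filter 145 and 280, normexp 565 and 845, slide as a random block 576 and 980 and array weights 1866 and 2129. The authors' values by the scanner files' genotypes gave 1686 higher and 1441 lower, so there the rises were more. That run counted the unmatched column of KO TAC replicate 4 as Cre TAC and did not hold the array of its scanner file. The median of all features was 0.079, and -0.12 with quantile normalization, -0.039 with median scaling, -0.049 with normexp and -0.060 without KO TAC replicate 4. Fitted on these 7 arrays alone, limma called 0 features, with 2422 at an unadjusted p under 0.05. The count of 786 became 68 without Cre TAC replicate 3, 127 without Cre TAC replicate 1, 390 without KO TAC replicate 3, 443 without KO TAC replicate 2, 482 without Cre sham replicate 2 and 510 without Cre sham replicate 1.

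**Figure D3:**
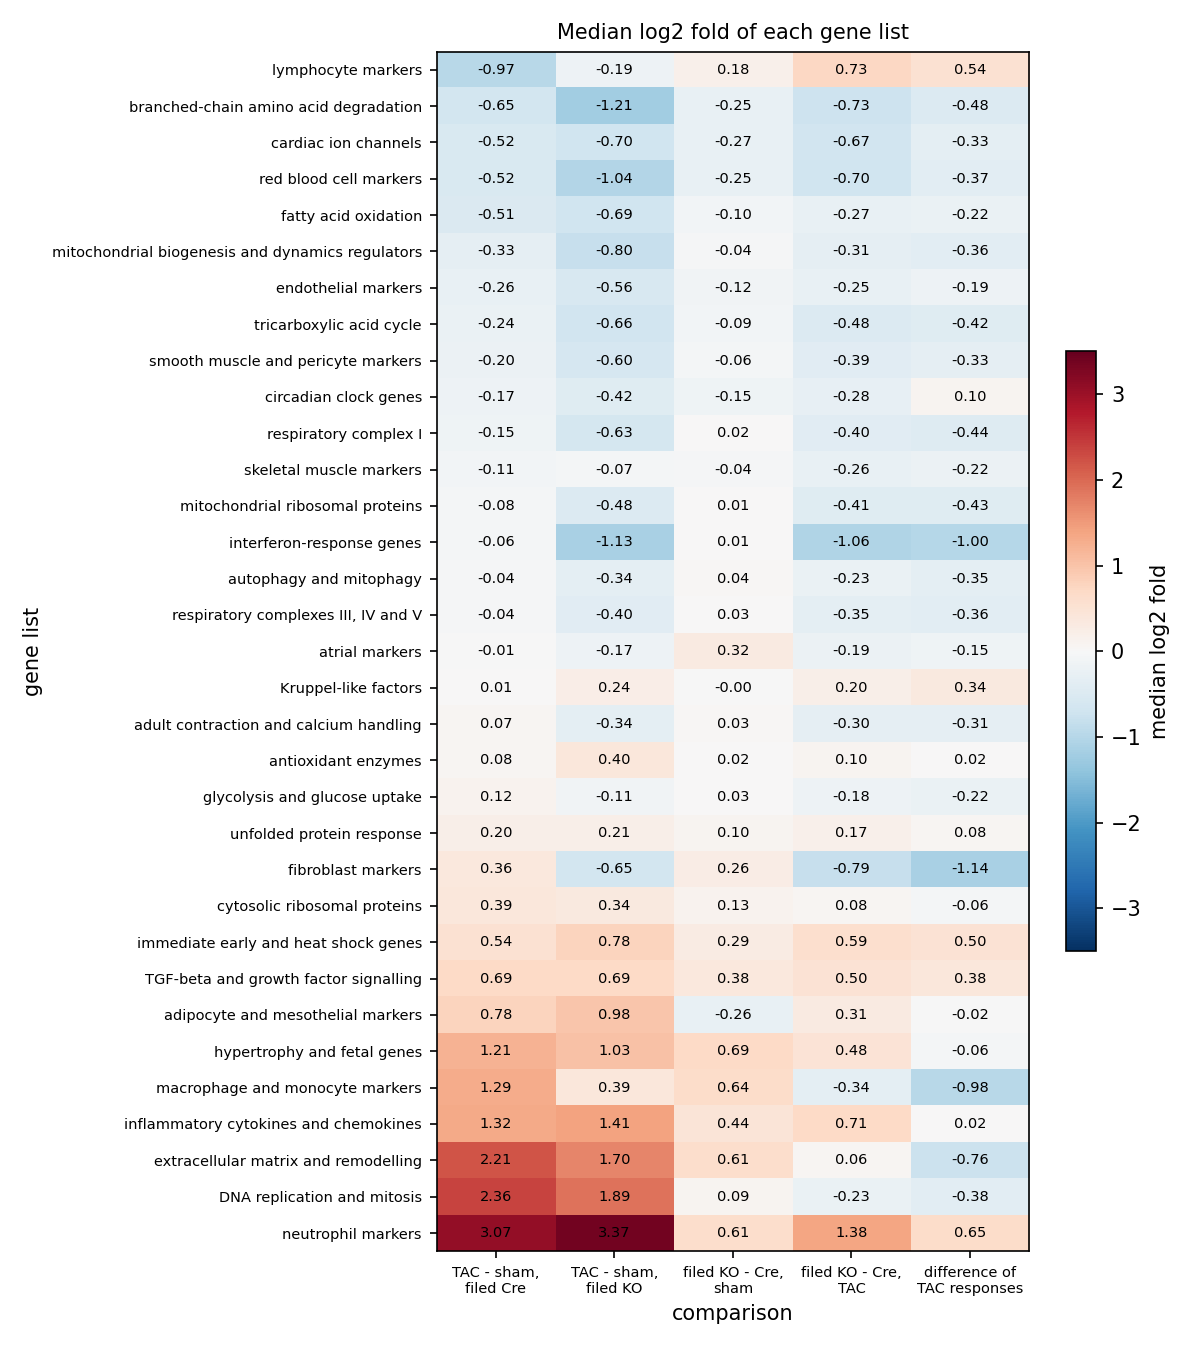
Median log2 fold (colour and printed value) of 33 gene lists (y axis) in the 5 comparisons (x axis), with groups as filed with the scanner files. Interferon-response genes had medians of -0.058 after TAC in arrays filed as Cre and -1.13 in arrays filed as KO.

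The last comparison tested whether the TAC response differed by genotype, as the response in arrays filed as KO minus that in arrays filed as Cre. Aqp8, a water channel, differed by -4.29 ± 0.52 (SE, adjusted p = 0.025), and the unnamed probe A_51_P197910 by -1.56 ± 0.20, adjusted p = 0.025. The unnamed probe A_52_P70888 passed with a positive sign (adjusted p = 0.025). It was well above background in TAC arrays filed as KO alone, so no size is given. In all, 3 of 25786 features passed (limma), with 1849 at an unadjusted p under 0.05. The call of Aqp8 ended for 12 of the 15 arrays left out 1 at a time, with an adjusted p up to 0.13 without Cre TAC replicate 3, where it was at -3.92. It did not pass with quantile normalization or a replicate block. The named probe of Aqp8 read 1.46 ± 0.31 (SD, n = 4) after sham and -1.89 ± 0.31 (SD, n = 4) after TAC in arrays filed as KO, and -0.17 ± 0.47 (SD, n = 4) and 0.77 ± 0.95 (SD, n = 3) in arrays filed as Cre. No list member passed. Interferon-response genes had a median log2 fold of -1.0, -0.95 with slide as a block and -1.54 to -0.41 within slides, camera adjusted p = 2.6e-18, adjusted p = 0.17 with an estimated correlation, with 14 of 24 adjusted over the list alone, and Ifit3 and Oas1a at -1.92 ± 0.42 and -1.44 ± 0.36. Fibroblast markers had a median log2 fold of -1.14, -1.18 with slide as a block and -1.15 to -0.61 within slides, camera adjusted p = 4.7e-12, adjusted p = 0.17 with an estimated correlation, with 6 of 18 adjusted over the list alone (9 without KO TAC replicate 4), and Islr and Dpt at -1.70 ± 0.30 and -1.36 ± 0.31. Macrophage and monocyte markers had a median log2 fold of -0.98, -1.03 with slide as a block and -1.28 to -0.37 within slides, camera adjusted p = 1.1e-09, adjusted p = 0.53 with an estimated correlation, with Ms4a7 at -1.99 ± 0.53 and Adgre1 at -1.41 ± 0.46. Extracellular matrix genes had a median log2 fold of -0.76, -0.83 with slide as a block and -1.28 to 0.22 within slides, camera adjusted p = 9.1e-07, adjusted p = 0.53 with an estimated correlation, with 1 of 37 adjusted over the list alone, Adamts4 at 1.90 ± 0.40 and Col14a1 at -2.03 ± 0.64. The matrix median was above 0 on 1 of 3 slides, and the other 7 lists had 1 sign. The probes of Col14a1 differed in sign, as did those of Mrps25. The other probes of Islr and Adgre1 were at -0.46 and -0.064. In the remaining lists 0 members passed adjusted over the list alone. Leaving out KO TAC replicate 4, 1 branched-chain gene did. Mitochondrial ribosomal proteins (median log2 fold of -0.43, -0.43 with slide as a block and -1.01 to -0.27 within slides, camera adjusted p = 9.5e-12, adjusted p = 0.53 with an estimated correlation) had Mrps25 at -1.27 and Mrpl34 at -0.89. Complex I (median log2 fold of -0.44, -0.46 with slide as a block and -0.78 to -0.46 within slides, camera adjusted p = 1.2e-08, adjusted p = 0.53 with an estimated correlation) had Ndufb5 at -0.97 and Ndufb3 at -0.78. Complexes III, IV and V (median log2 fold of -0.36, -0.39 with slide as a block and -0.71 to -0.31 within slides, camera adjusted p = 5.8e-06, adjusted p = 0.53 with an estimated correlation) had Cox8b at -0.74 and Uqcrh at -0.43. Branched-chain amino acid genes (median log2 fold of -0.48, -0.44 with slide as a block and -0.89 to -0.57 within slides, camera adjusted p = 1.6e-05, adjusted p = 0.53 with an estimated correlation) had Oxct1 at -1.38 and Hibch at -0.87. Ppargc1a, Nppa, Nppb, Myh7, Acta1, Esrra and Klf4 differed by -1.42, -1.50, -0.93, -1.09, -1.16, -0.41 and 0.061, none past the threshold. Smooth muscle and pericyte markers were a lower list too (median log2 fold of -0.33, camera adjusted p = 0.0056, adjusted p = 0.53 with an estimated correlation), with a camera adjusted p of 0.44 without KO TAC replicate 4. Camera set 1 of 33 lists higher and 15 lower, and 6 and 10 without KO TAC replicate 4. There the medians of mitochondrial ribosomal proteins, complex I, complexes III, IV and V and branched-chain genes were -0.24, -0.27, -0.18 and -0.25. The matrix median was -0.47 without Cre TAC replicate 2. Without KO TAC replicate 4, 6 features were higher and 25 lower, and with slide as a block 6 and 12, each with all 3 among them. Quantile normalization gave 2 and 10, normexp 2 and 9, median scaling 2 and 1 and the authors' values by the scanner files' genotypes 90 and 85, of which 0, 1, 2 and 2 were among the 3, and quantile normalization moved the median of all features from 0.058 to -0.12. The count was 31 without KO TAC replicate 4, 22 without Cre TAC replicate 2, 1 without replicate 1 of Cre sham, Cre TAC or KO sham, and 0 without Cre sham replicates 2, 3 or 4, Cre TAC replicate 3, KO sham replicates 2, 3 or 4, or KO TAC replicates 2 or 3, where 1408 to 2103 features had an unadjusted p under 0.05 in limma.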

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

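All tests of explanations in this part were chosen after the results were seen. A sample counted as standing apart when its gap to the nearest other sample exceeded Dixon's 95% critical share of its group's range in a group of 4, which chance gives in about 1 of 20 groups. Of 21 quality measures 4 did so, and of 291 pairs of a named gene and a group 24 did, where 1 in 20 would be 14.6.

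KO TAC replicate 4 stood apart in its median signal (a gap of 0.938 of the range), its share of probes above background (0.919) and its 96 nonuniform spots (0.936). The other arrays had at most 8 such spots. The median signal of KO sham replicate 1, 88.2, stood apart as well (0.841). A response of the group to TAC is argued against for replicate 4, since the highest share among the other 3 arrays of its group was 72.2% and arrays of the other groups reached 75.7%. A raised background over the whole array cannot be judged from its negative control signal. That signal of 4.31 lay within the 2.28 to 4.94 of the others, but it was read after background subtraction. Labelled material that is not heart RNA may be the source: 82.0% of the 6765 probes dark on the 14 other arrays were above background there. Of 33 gene lists, lymphocyte markers lay furthest above the other KO TAC arrays there, by a median of 2.04, followed by skeletal muscle markers at 0.42. Whether this came from lymphocytes or from dim probes of any kind being raised was not tested. Binding to unintended probes would light dark probes as well, so these cannot be told apart.

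The genotype labels of the scanner files and of the value table were exchanged for 14 arrays. Either may carry the exchange. By each source's own labels Klf4 differed between KO and Cre after sham by -0.045 in the scanner files and 0.11 in the value table, both within their SE of 0.27 and 0.19, so which source is wrong cannot be told apart, and the probe may lie outside the deleted part. The RNA may also hold Klf4 from cells in which cre was not active. The scanner file of KO TAC replicate 4 matched no column of the table. The column of KO TAC replicate 4 matched no scanner file, its highest rank correlation being 0.990 with the file of Cre TAC replicate 2. No biological explanation was tested.

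Among named genes, 1 array at a time of the sham group filed as Cre stood apart for Ccnb1 (0.881), Clec4d (0.858), Cox8b (0.91), Idh2 (0.951), Il1r2 (0.838), Lrrc52 (0.933), Ndufb3 (0.911), Nppa (0.867), Ogdh (0.9987), Uqcrh (0.866), given as the gap over the range. In the sham group filed as KO this held for Ccnb1 (0.957), Chil4 (0.883), Clec4e (0.907), Esrra (0.945), Oas1a (0.887), Retnla (0.849), Rpl22l1 (0.899), and in the TAC group filed as KO for Dbp (0.849), Fgf21 (0.894), Ms4a7 (0.833), Nppb (0.881), Ogdh (0.857), Ppm1k (0.924), Slc6a19 (0.898). KO TAC replicate 4 was that array for 2 of these. The TAC response differed between genotypes, by the test of the difference itself, for Aqp8 (-4.29) and for 2 unnamed probes, A_51_P197910 (-1.56) and A_52_P70888, each at an adjusted p of 0.025 in limma. The fitted 4.51 of A_52_P70888 is not a measured size, since the probe was well above background in TAC arrays filed as KO alone. The call of Aqp8 ended for 12 of the 15 arrays left out 1 at a time, and none of the 3 passed with quantile normalization (12 others did) or with a replicate block, where limma called 0 with 1550 at an unadjusted p under 0.05.

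Other splits of the same arrays bear on the counts. For TAC in arrays filed as Cre, 1 of 35 splits, the real one, gave 1532 calls, a share of 0.029, and the highest other gave 1. For TAC in those filed as KO, 1 of 35 splits gave 5978, also a share of 0.029, and the highest other 1. This is the smallest share that 35 splits can give. These splits ignored slides, and none was run within slides for TAC, so chance is argued against but not excluded. For genotype after sham 2 of 35 splits gave 4 or more calls, so over all splits chance cannot be excluded for the count. The highest other gave 250 and set the arrays of slides 2 and 3 against those of slides 1 and 4, a structure of the samples. With slide as a block there were 4 calls, 3 of them among the 4 reported. With genotype reassigned only within slides there were 8 splits, too few for a share under 0.05, where the real one gave 4 and the highest other 0. The 4 features had the same sign in the TAC arrays, which these splits did not regroup. TAC means filed as Cre and as KO were 0.28 and 1.32 for Hdhd3 and -5.05 and -7.84 for A_52_P908036. They were -0.79 and -4.08 for A_51_P370073 and -3.48 and -5.68 for A_52_P458141, with SDs up to 0.65. For these 4 features, not for the count, this argues against chance. For genotype after TAC 2 of 35 splits gave 786 or more, so over all splits chance cannot be excluded. The highest other gave 882 and set KO TAC replicate 4 with the arrays filed as Cre. It was the only other split to reach 786. It moved that array alone, so it kept the genotype grouping of the remaining TAC arrays. Within slides the 8 splits were again too few, the real one giving 786 and the highest other 197. For the difference of responses 4 of 100 drawn splits gave 3 or more calls, a share of 0.04, and 1 of them gave 307. What sets that split apart was not tested. Within slides 6 of 100 drawn splits gave 3 or more, the highest other giving 421, so there chance cannot be excluded.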

How the results depend on the processing

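Slide block without that replicate and the authors' values under the scanner files' genotypes were chosen after seeing the data, and unless stated the cause of a change was not tested. Of the alternatives other than leaving out 1 array, 115 counts stayed within 1.5 times and 59 did not, 528 list shifts kept direction and side of the threshold, 48 lost the call and 24 reversed, and for named genes 2085 kept direction and side, 71 lost the call, 41 gained it and 91 reversed. In the order TAC filed as Cre, TAC filed as KO, genotype after sham, genotype after TAC and difference of responses, array weights gave 4097, 10528, 704, 3995 and 496 calls and slide block without KO TAC replicate 4 gave 5690, 10699, 14, 4240 and 271. The authors' values under their own labels gave 8637 in the first, 38 (25 higher, 13 lower), 3127 and 175 in the last 3, and under the scanner files' genotypes 5865 in the first, 38, 3127 and 175. Normexp gave 1410 for genotype after TAC and 11 (2 higher, 9 lower) for the difference of responses. Quantile normalization gave 2 (1 higher, 1 lower) after sham and 12 for the difference, and median scaling 799 for TAC filed as Cre and 238 for genotype after TAC. No filter gave 425 for genotype after TAC, and the filter on all 15 arrays, which tests fewer features, 2 after sham and 5 for the difference. Slide as a block gave 1369 for genotype after TAC and 18 for the difference, and slide as a random block 2342, 7, 1556 and 17 for all but TAC filed as KO. The mean over probes and trended robust variance gave 6 and 8 for the difference. Only the compared groups, with fewer arrays, gave 3134 for TAC filed as KO and 0 for genotype after TAC. The operation of the description field gave 0, 0, 0, 2 and 0 by limma, with 40, 2514, 921 and 469 at an unadjusted p under 0.05 where it gave 0. The replicate block gave 935 for TAC filed as Cre, 302 for genotype after TAC, 0 for the difference (1550 at an unadjusted p under 0.05) and 816 features called in both TAC responses. Replicate numbers do not pair the arrays: 9 of 21 same-numbered pairs had correlated deviations over 0.1. Features called in both TAC responses were 1263 as reported, 652 with median scaling, 4376 with the authors' values under either genotype labels, 3387 with array weights and 4297 with slide block without KO TAC replicate 4. The numbers of shifted lists after sham were 18 with normexp and 17 with the authors' values, also under the scanner files' genotypes. With an estimated correlation 0 lists passed in each of the 5 comparisons, with 7, 5, 4, 3 and 2 at an unadjusted p under 0.05. Random slide blocks were not run for lists. Leaving out 1 array ended 123 calls of named genes, added 4 and reversed 14 values. It gave 413 to 3486, 4490 to 8109, 4 to 8, 68 to 2277 and 0 to 31 calls, and 377 to 2763 called in both TAC responses. The Klf4 difference ran from -0.23 to 0.18 after sham and from -0.10 to 0.23 after TAC, from -0.013 to 0.42 for TAC filed as KO and from -0.17 to 0.27 for the difference of responses, and Nppa after TAC from -0.026 to 0.13. Klf4 between genotypes after TAC was -0.10 with median scaling, where Nppa was -0.066 and the Klf4 difference of responses -0.086. Nppa was -0.074 with slide block and -0.17 with slide block without KO TAC replicate 4. The authors' values under their own genotype labels, which are exchanged relative to the scanner files, reversed the genotype differences. Klf4 was 0.11 after sham and -0.14 after TAC. TAC in the columns labelled Cre, which hold arrays filed as KO, gave Myh7 -0.17 and Ppargc1a -0.90, and in the columns labelled KO 0.49 and 0.36. By the scanner files' genotypes, with the unmatched column of KO TAC replicate 4 counted as Cre TAC, these 4 values kept the sign reported. After sham the values were Hdhd3 -1.46, Nppa -1.43, Nppb -1.08, Myh7 -0.30, Acta1 -1.52, Ppargc1a 0.51, Esrra 0.19, Tnc -2.12, Cilp -1.73, Ankrd1 -0.88, Mpeg1 -1.20, Ms4a7 -0.96, Serpina3n -2.37, Il1rn -1.02, Rpl3 -0.59, Rps27l -0.21, Bcat2 0.45, Ppm1k 0.39, Fstl1 -0.86, Fgf21 -1.05, Clec4d -1.82, Clec4e -0.75. After TAC they were Cxcl3 -2.86, Cxcl2 -1.51, Csf3 -1.34, Masp1 -1.48, Fam24b -2.26, Lce1f -2.20, Slc6a19 -1.17, P2ry10 -0.60, Gbp6 2.96, Fn3k 2.99, Lrrc52 1.31, Ip6k3 2.43, Asb10 2.58, Papln 0.70, Aqp8 2.42, Pacsin1 2.36, Nppa -0.092, Nppb -0.58, Myh7 0.36, Acta1 -0.61, Ppargc1a 1.77, Esrra 0.43, Ifit3 1.16, Cmpk2 1.04, Mrps25 0.98, Oxct1 1.07, Ppm1k 1.01, Ndufb5 0.78, Ogdh 0.92, Islr 1.33, Fbln1 1.22, Esrrb 1.11, Atp5d 0.34, Uqcrc2 0.37. For the difference of responses they were Aqp8 3.97, Klf4 -0.25, Nppa 1.34, Nppb 0.50, Myh7 0.66, Acta1 0.90, Ppargc1a 1.26, Esrra 0.24, Ifit3 1.47, Oas1a 1.10, Islr 1.37, Dpt 1.13, Mrps25 1.03, Mrpl34 0.78, Ms4a7 1.85, Adgre1 1.27, Ndufb5 0.80, Ndufb3 0.53, Adamts4 -1.59, Col14a1 1.99, Cox8b 0.49, Uqcrh 0.14, Oxct1 1.01, Hibch 0.75. List medians reversed after sham were extracellular matrix and remodelling -0.52, hypertrophy and fetal genes -0.49, macrophage and monocyte markers -0.58, inflammatory cytokines and chemokines -0.36, cytosolic ribosomal proteins -0.011, branched-chain amino acid degradation 0.29, TGF-beta and growth factor signalling -0.33, neutrophil markers -0.41, after TAC interferon-response genes 0.86, mitochondrial ribosomal proteins 0.25, branched-chain amino acid degradation 0.57, respiratory complex I 0.26, tricarboxylic acid cycle 0.34, fibroblast markers 0.64, mitochondrial biogenesis and dynamics regulators 0.26, respiratory complexes III, IV and V 0.21 and for the difference interferon-response genes 0.82, fibroblast markers 0.95, mitochondrial ribosomal proteins 0.19, macrophage and monocyte markers 0.92, respiratory complex I 0.21, extracellular matrix and remodelling 0.67, respiratory complexes III, IV and V 0.13, branched-chain amino acid degradation 0.23. Signal over background limits the dim genes. In the main fit they are given as bounds where no array of the lower of 2 groups read them well above background. Where only some arrays of that group did, log2 differences are given, and their sizes depend on the background.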

Other observations

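The test of genes near Klf4 and the choice of genes named in this part were made after the results were seen. Members of other gene lists changed after TAC. Of 21 cardiac ion channel genes 10 fell in arrays filed as KO (camera adjusted p = 4.6e-05, adjusted p = 0.28 with an estimated correlation) and 2 in those filed as Cre (camera adjusted p = 0.0037, adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone these were 11 and 2. Leaving out KO TAC replicate 4, 9 fell and 1 rose in arrays filed as KO, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00044, adjusted p = 0.34 with an estimated correlation). In those filed as Cre 6 fell there, 7 adjusted over the list alone (camera adjusted p = 0.0024, adjusted p = 0.46 with an estimated correlation). Of 19 circadian clock genes 7 fell and 4 rose in arrays filed as KO, 8 and 4 adjusted over the list alone (camera adjusted p = 0.096). In those filed as Cre 5 fell, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.15 with an estimated correlation). In the fit that left out KO TAC replicate 4, 8 clock genes fell and 5 rose in arrays filed as KO and 6 fell and 1 rose in those filed as Cre. Of 28 antioxidant enzymes 10 rose and 2 fell in arrays filed as KO, 12 and 6 adjusted over the list alone (camera adjusted p = 0.16). Of 23 genes of the unfolded protein response 5 rose and 4 fell there, 6 and 4 adjusted over the list alone (camera adjusted p = 0.35). Leaving out KO TAC replicate 4, 11 antioxidant enzymes rose and 1 fell (camera adjusted p = 0.018, adjusted p = 0.32 with an estimated correlation). There 12 genes of the unfolded protein response rose and 5 fell (camera adjusted p = 0.0046, adjusted p = 0.34 with an estimated correlation).

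Without KO TAC replicate 4, 31 features passed the test of the difference of responses. Named genes among them, chosen after their values were seen, included Zbp1 (-2.67 ± 0.41, SE), C3 (-1.93 ± 0.26), Gbp6 (-4.0 ± 0.54), Pipox (-2.84 ± 0.30), Sesn1 (-1.99 ± 0.31) and Glrx (1.35 ± 0.21), with limma adjusted p from 0.0098 to 0.042. The chemokine Cxcl2 was among them with a positive sign (adjusted p = 0.048). It was well above background in TAC arrays filed as KO alone, so no size is given. No gene group was tested among the 31. Zbp1 changed by 1.99 after TAC in arrays filed as Cre and by -0.67 in arrays filed as KO.

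A hypothesis from the data is that donor strain DNA beside Klf4 may account for part of the genotype differences, since genes on chromosome 4, where Klf4 lies in the GRCm38.p6 gene table, recurred among them. It was tested only after this was seen, without KO TAC replicate 4, on 7 rankings of 14878 genes, each with a window test (51 consecutive genes, 10000 random gene orders) and a Fisher's exact test of the chromosome, two-sided, and all 14 tests are adjusted together. The first ranking tried, by the mean genotype difference over sham and TAC, showed nothing: its top 200 genes had 16 on chromosome 4 where 12.4 were expected (Fisher's exact test, adjusted p = 0.38), and the fullest window had a permutation p of 0.99. The other 6 were tried after that. Ranked by the sham difference, the top 50, 100 and 200 genes had 12, 19 and 29 on the chromosome where 3.11, 6.22 and 12.4 were expected (adjusted p = 0.00020, 0.00014 and 0.00014). Ranked by both differences of 1 sign they had 6, 12 and 18 (adjusted p = 0.18, 0.067 and 0.16). No window test passed, the smallest adjusted p being 0.060. So 3 of the 14 tests passed, all from 1 ranking, and the fullest window lay within 500 genes of Klf4 alone in 5 of the 7 rankings. Chromosome 4 held 926 of the genes placed. A reach of 500 genes either side spans much of it, so this does not place a cluster beside Klf4. Chance clustering and strain DNA cannot be told apart, because the outcome depends on the ranking, neighbouring genes are not independent, and an effect of Klf4 loss on nearby genes was not tested.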
